A study of Mus musculus with 2 samples.

How the data were processed

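Single-cell RNA libraries of bone marrow were made on the BD Rhapsody whole-transcriptome platform from male mice, whose strain the labels give as C57B/6. The mice ate normal chow (ND) or a diet with 60% fat (HFD) for 16 weeks. There was 1 library per diet. The labels name neither the number of animals behind a library nor any pooling, and they name no sort or gate, so the shares below describe the cells loaded, and an unstated enrichment is not excluded. The deposited tables hold counts, that is RSEC-corrected molecules (UMIs) per gene and cell, which the authors made with the BD WTA Rhapsody Analysis Pipeline 1.9.1 per the file headers. The headers name a custom reference. Its genome build and annotation release are not given in the sources used here, so no coordinates are given. All deposited values were whole numbers. The same tables hold molecules of 5 antibody tags per cell.

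Genes were matched between the libraries by symbol. The tables held 22229 (ND) and 22263 (HFD) genes and shared 20478 of 24014 symbols, and a symbol absent from one table was taken as 0 there. Cells with at least 200 genes and at most 25% mitochondrial UMIs were kept. Scrublet doublets, computed within each library with an expected rate of 5%, were removed. Both libraries were clustered together in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9) without batch integration. Counts were scaled to 10000 UMIs per cell and logged, and 2000 variable genes, 30 principal components and 15 neighbours fed Leiden clustering at resolution 1.0, which gave 31 clusters. A cluster took the name of the class with the most markers among its top 50 genes by fold over all other cells (pseudocount of 10 CPM, detected in at least 10% of its cells). At least 3 markers were needed, and the top 10 genes had to hold no more markers of another class. Classes are called X-like because only these markers name them. 3 clusters stayed unnamed. The stage of neutrophil cluster 25 was taken from its top 10 genes, a rule added after the data were seen.

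Shares of cells carry exact Clopper-Pearson 95% intervals. Within a class, UMIs were summed over cells and scaled to the class total (CPM), and the log2 ratio of HFD over ND was taken with an exact conditional binomial 95% interval. A count of 0 stood at a floor of 3. With 1 library per diet no test was possible, so no p-value is given. All intervals and floors cover counting error only, not differences between animals or preparations. The intervals of log2 ratios also leave out the clustering of UMIs within cells. A gene was called higher or lower in the HFD library when the ratio was at least 1.5-fold and its interval excluded 0. This describes these libraries only.

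Markers of 19 cell classes, 30 gene lists, the comparisons and the alternatives were fixed before the data were examined. List members needed 20 UMIs over both libraries in the class. A list is given by the median log2 ratio of its members, with an order-statistic 95% interval, and by its place among 10000 random lists matched on expression. Genes named were the 10 highest and 10 lowest log2 ratios in neutrophil-like cells, and the 5 highest and 5 lowest in each other class with at least 100 cells in both libraries, among genes with at least 200 UMIs. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor genes were left out of these rankings, as were numbered gene models and genes under 10% of the level of another class in both libraries. Up to 4 members of each list with the largest ratios were named, with S100a8, S100a9, Xist, Ddx3y and the haemoglobin genes always. Other genes named, including those followed across the 16 classes compared, were chosen after their values were seen. Results of some genes that met these rules are not reported.

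Alternatives changed the cell filter (all cells, or at least 500 genes and at most 15% mitochondrial UMIs), doublet removal, Leiden resolution (0.5, with 25 clusters, and 2.0, with 47), the scaling (median-of-ratios size factors, totals without mitochondrial, haemoglobin, S100a8 and S100a9 UMIs, a mean over cells, cells thinned to 1000 UMIs, or neutrophil stages weighted alike, with the floor where a stage held 0 UMIs) and the minimum for list members (100 or 1 UMI). Leaving out neutrophil cluster 25 was an alternative chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.

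The ratios were tested on simulated data, Poisson counts with the real means and library sizes and 200 changed genes. The intervals assume such counts, so coverage near 95% was fixed by this setting and checks only the computation. Clustering of UMIs within cells of unlike depth was not simulated, so intervals of the real sums may be too narrow. In simulated neutrophil-like sums of 12549 genes, a 2-fold change gave a median log2 ratio of 1.00, intervals held the true value for 94.9% of 9639 unchanged genes, and 100% of the 66 genes changed 2-fold but 45.1% of the 71 genes changed 1.5-fold were called. None of the unchanged genes was called. In simulated HSPC-like sums of 11378 genes these values were 1.01, 95.3% of 7192, 100% of 66 and 52.1% of 71, and 0.056% of the unchanged genes were called. Of 100 unchanged random lists of 20 genes, 5% and 4% lay outside the central 95% of matched lists.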

Results

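Bone marrow cells of mice on normal chow (ND) and on a high-fat diet (HFD) were profiled in 1 library per diet, to compare how the diet goes with the make-up of the marrow and with gene expression in neutrophils and blood-forming progenitors. The ND library held 16817 cells with 117999042 RNA UMIs and a median of 3644 per cell. The HFD library held 17282 cells with 117773643 RNA UMIs and a median of 3626 per cell. The filter removed 2515 ND cells (15%, 95% interval 14.4 to 15.5%) and 1632 HFD cells (9.44%, 9.01 to 9.89%), and doublet removal took 420 and 465 more. 13882 ND cells with a median of 4478 UMIs and 15185 HFD cells with a median of 4068 remained. Their median mitochondrial shares were 7.08% and 6.21%. Xist, the transcript of the inactive X chromosome, had 14 and 7 UMIs in the ND and HFD libraries, while Y-linked Ddx3y had 9136 and 9933.

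Neutrophil-like, monocyte-like and B cell-like cells made up more of the HFD library, and HSPC-like (stem and progenitor), macrophage-like, NK cell-like and erythroid-like cells less. Neutrophil-like cells were 20.6% of ND cells (19.9 to 21.2%) and 25.9% of HFD cells (25.2 to 26.6%), a ratio of 1.26 (1.20 to 1.32). Monocyte-like cells were 7.96% and 12.4% (ratio 1.56, 1.45 to 1.69), and B cell-like cells 7.75% and 8.84% (1.14, 1.05 to 1.24), or 3.63% and 4.23% at Leiden resolution 2.0, with a ratio of 1.17. NK cell-like cells were 3.0% and 1.47% (0.49, 0.41 to 0.58), erythroid-like cells 8.0% and 5.34% (0.67, 0.61 to 0.73), HSPC-like cells 4.66% and 3.65% (0.78, 0.70 to 0.88) and macrophage-like cells 12.4% and 10% (0.81, 0.75 to 0.87).

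The monocyte-like cells lay in 2 clusters, and the cluster that held most of them differed between the libraries. Cluster 8, with the classical monocyte genes Ccr2 and Fn1 among its top genes, held 56.7% of the ND and 43.2% of the HFD monocyte-like cells. Cluster 24, with the patrolling monocyte genes Ace and Nr4a1, held 43.3% and 56.8%. As a share of all cells, cluster 8 was 4.52% and 5.38%, and cluster 24 was 3.44% (3.15 to 3.76%) and 7.07% (6.66 to 7.49%). Median depth was 7088 and 7684 UMIs in cluster 8 and 2803 and 2760 in cluster 24. Among macrophage-like cells, the low-depth cluster 19 (median 909 and 911 UMIs) was 8.36% and 6.25% of cells, and cluster 21 was 4.01% and 3.75%.

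Eosinophil-like cells were 2.06% and 2.56% (ratio 1.24, 1.06 to 1.45), plasmacytoid dendritic cell-like cells 3.83% and 3.19% (0.83, 0.74 to 0.94), basophil or mast cell-like cells 10.5% and 9.38% (0.90, 0.83 to 0.97) and megakaryocyte-like cells 1.05% and 0.744% (0.71, 0.55 to 0.91). Pro- and pre-B cell-like cells were 0.648% and 0.882% (1.36, 1.03 to 1.80), but 4.74% and 5.47% at resolution 2.0, where part of the B cell-like cells took this name and the ratio was 1.15. The intervals of the ratio included 1 for T cell-like cells (4.49% and 4.19%), conventional dendritic cell-like cells (3.90% and 3.48%), plasma cell-like cells (1.02% and 0.896%) and stromal cell-like cells (11 and 10 cells). Shares sum to a fixed total, so a higher share of one class lowers the others. Out of cells that were not neutrophil-like, the ratio was 0.84 for HSPC-like, 0.52 for NK cell-like, 0.72 for erythroid-like and 1.68 for monocyte-like cells. The intervals of that ratio included 1 for plasmacytoid dendritic cell-like (0.89, 0.79 to 1.01) and basophil or mast cell-like cells (0.96, 0.89 to 1.04).

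**Figure D1:**
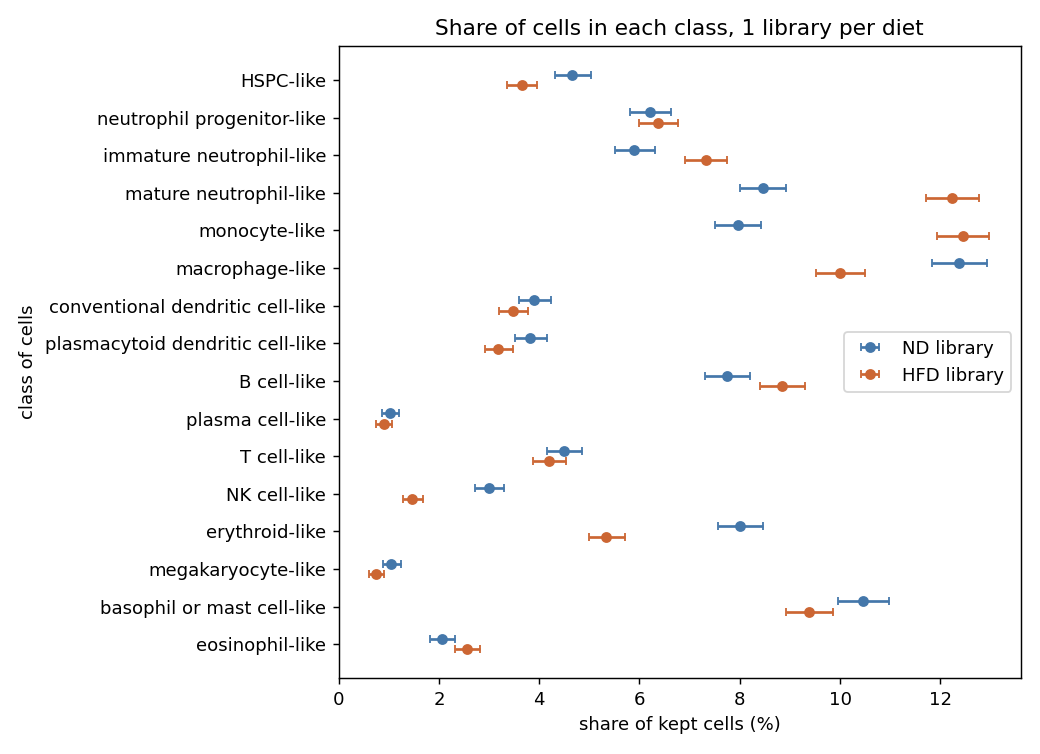
Share of kept cells (%) in each class in the ND and HFD libraries; bars are exact 95% intervals of counting error. Mature neutrophil-like cells stood at 8.46% in the ND and 12.2% in the HFD library, and NK cell-like cells at 3.0% and 1.47%.

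Within the neutrophil-like cells the mix of stages was shifted towards the mature end in the HFD library. Mature neutrophil-like cells were 41.1% of the 2855 ND neutrophil-like cells (39.3 to 43.0%) and 47.2% of the 3939 HFD ones (45.6 to 48.8%), a ratio of 1.15 (1.07 to 1.24). Neutrophil progenitor-like cells were 30.2% and 24.6% (0.81, 0.74 to 0.89), and immature neutrophil-like cells 28.7% and 28.2% (0.98, 0.90 to 1.08). As a share of all cells, progenitor-like cells were 6.21% and 6.37%, immature cells 5.90% and 7.32%, and mature cells 8.46% and 12.2%. The mature stage held the most cells in cluster 29 in both libraries (51.5% and 54.4% of the stage). Cluster 25, which carried markers of both the immature and the mature stage, was 27.1% and 20.2% of the mature cells. Ratios of genes within the mature stage may therefore also carry its cluster mix. Median depth fell along the stages, from 21624 and 21904 UMIs in progenitor-like to 2854 and 2558 in mature cells, so ratios over all neutrophil-like cells also carry the stage mix.

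The study's question of phagocytosis and bacterial killing was addressed with a list for each step, and the median of the phagocytosis receptors stood near 0 within every stage. Phagocytosis receptors, which bind opsonised or bare microbes, had a median log2 ratio of 0.13 (-0.03 to 0.27, 23 genes) over all neutrophil-like cells. It was -0.00084 in progenitor-like, 0.02 in immature and 0.07 in mature cells, and -0.0059 with the stages weighted alike, although over all stages the list lay above the central 95% of matched random lists. Cd36, a scavenger receptor, was the only receptor higher (2.19, 1.51 to 2.94, with 21 and 117 UMIs), and C3ar1, a complement receptor, the only one lower (-1.80, -3.29 to -0.50, with 20 and 7 UMIs). Cd36 was also among the top genes of monocyte-like cluster 24. The Fc receptor gene Fcgr3 was at 0.03 (-0.02 to 0.07) and the integrin gene Itgam at 0.11 (0.08 to 0.14). In mature cells Tlr4, the endotoxin receptor, was higher (0.78, 0.34 to 1.24), and its co-receptor Cd14 (-0.79, -1.47 to -0.11) and Clec4n (-1.27) were lower.

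The machinery behind uptake and killing showed no member past the size rule over all neutrophil-like cells. Phagocytic signalling and actin genes had a median of 0.11 (0.06 to 0.17, 35 genes, 31 above 0), with Coro1a, a coronin of the actin cortex, at 0.45 (0.43 to 0.47) and the formin Fmnl1 at 0.41 (0.35 to 0.47). Phagosome and lysosome genes stood at 0.05 (-0.00092 to 0.12, 33 genes) and the NADPH oxidase, which makes superoxide, at 0.14 (-0.0018 to 0.20, 11 genes). Cybb, its catalytic subunit, was at 0.09 (0.06 to 0.11) over all stages and at -0.26 (-0.30 to -0.22) in mature cells. Primary granule genes were at -0.05 (-0.14 to 0.23), with Mpo at -0.08 (-0.09 to -0.07). Extracellular trap genes were at 0.01 (-0.04 to 0.18), with Padi4 at 0.32 (0.24 to 0.40). With the stages weighted alike, the medians were 0.08 for signalling and actin, 0.02 for phagosome and lysosome, 0.05 for NADPH oxidase, and 0.13 for both the primary granule list, which turned sign, and the trap list. In the mature stage, medians were 0.06 for signalling and actin, -0.02 for phagosome and lysosome, 0.0086 for NADPH oxidase, 0.28 (-0.16 to 0.54) for primary granules and 0.17 (-0.12 to 0.46) for trap genes.

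Secondary and tertiary granule genes differed by stage. Their median was 0.14 (0.09 to 0.20, 24 genes) over all neutrophil-like cells, 0.33 (0.16 to 0.59) in progenitor-like, 0.02 in immature and -0.12 (-0.18 to 0.00030) in mature cells. Cluster 25, with the list members Mmp8, Mmp9 and Retnlg among its top genes, held 27.1% of ND and 20.2% of HFD mature cells. Part of the mature value may lie in this mix. In progenitor-like cells 5 members were higher, all granule proteins of later stages: Ngp (1.63, 1.52 to 1.74), Olfm4 (1.27), Ltf (1.05), Lcn2 (0.72) and Chil3 (0.59). S100a8 was at 0.36 and S100a9 at 0.49 in the same cells. The list had a like median, 0.43, over the 13 classes outside the neutrophil stages, so the value in progenitor-like cells is not particular to them. The median of the list over all stages moved to 0.03 with every cell weighted alike.

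**Figure D2:**
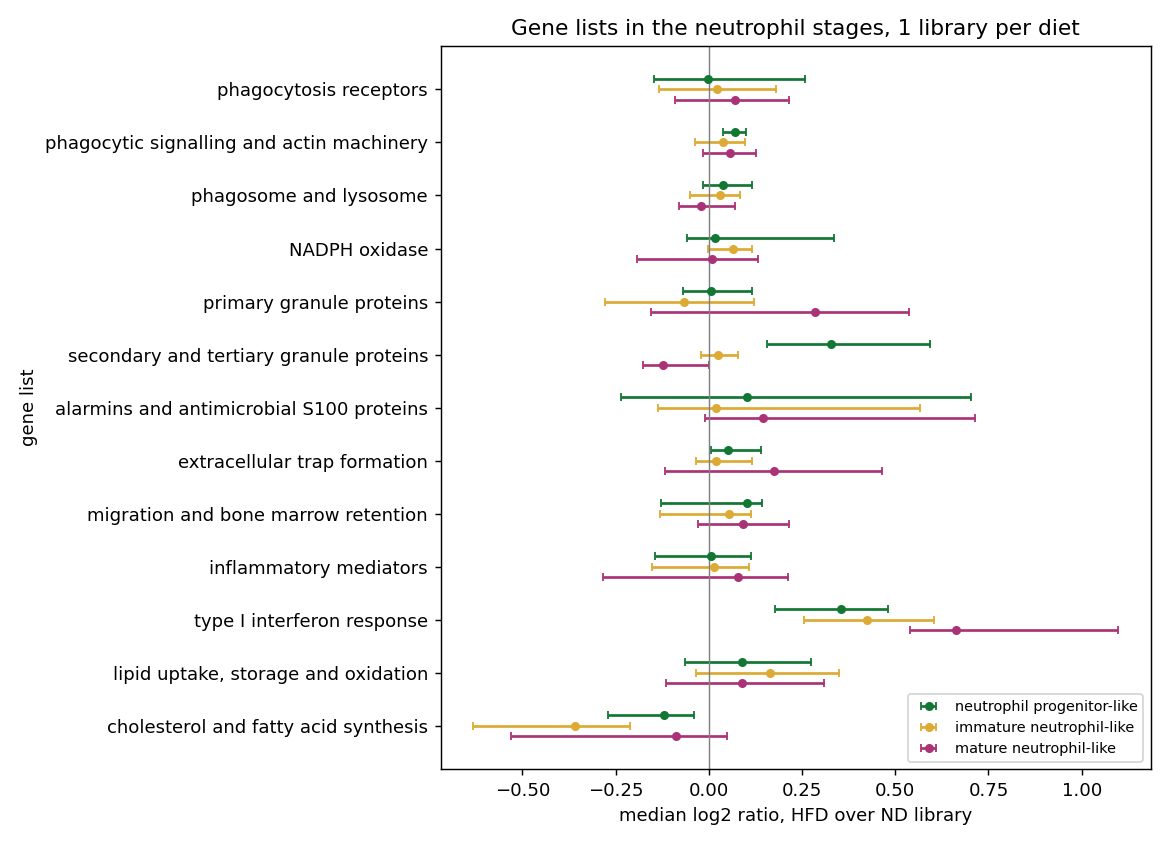
Median log2 ratio of HFD over ND for 13 gene lists in the progenitor-like, immature and mature neutrophil-like cells; bars are order-statistic 95% intervals over list members. The type I interferon list lies at 0.35, 0.42 and 0.66 in the 3 stages, and the phagocytosis receptors at -0.00084, 0.02 and 0.07.

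The widest difference among the neutrophil lists was in the type I interferon response, the genes switched on by interferon alpha and beta. Its median was 0.69 (0.45 to 0.83), 17 of 31 members were higher and none lower, and the list lay above all matched random lists. Oasl2 (1.43, 1.27 to 1.60), Rtp4 (1.44, 1.20 to 1.68), Isg15 (1.22, 0.93 to 1.51) and Ifit1 (1.83, 1.40 to 2.28) were among the 10 highest genes of the class. The median was 0.35 in progenitor-like, 0.42 in immature and 0.66 (0.54 to 1.10) in mature cells, where 15 of 28 members were higher, and 0.44 with the stages weighted alike. The interferon gamma and class I antigen presentation list was at 0.17 (0.06 to 0.22), with only Iigp1 higher (2.17, 6 and 33 UMIs), and MHC class II genes at -0.17 (-0.53 to 0.05).

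Some genes of fatty acid use were higher and Sqle, of sterol synthesis, was lower in neutrophil-like cells of the HFD library, while most members of these lists did not pass the size rule. Acot1, a cytosolic acyl-CoA thioesterase, stood at 1.77 (1.62 to 1.93) over all stages and at 2.86 (2.52 to 3.22) in mature cells. Cpt1a, the gate of mitochondrial fatty acid import, was at 0.59 (0.53 to 0.66) and Plin2, a lipid droplet coat protein, at 0.61 (0.49 to 0.73). In mature cells Plin2 was at 1.02, Cpt1a at 1.07 and the carnitine carrier Slc25a20 at 1.11. The lipid uptake, storage and oxidation list had a median of 0.10 (0.02 to 0.25), or 0.04 with the stages weighted alike, with 5 of 33 members higher and 1, Acsl3, lower. The cholesterol and fatty acid synthesis list had a median of -0.19 (-0.32 to -0.09, 25 genes). Sqle, the squalene epoxidase of cholesterol synthesis, stood at -0.78 (-0.99 to -0.56).

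Heat shock genes gave the largest ratios of the class. Hspa1a (4.06, 3.74 to 4.40, with 82 and 1669 UMIs) and Hspa1b (4.13, 3.85 to 4.41) encode the inducible Hsp70. Their summed UMIs stood at 4.19 (3.98 to 4.41) in progenitor-like and 4.43 (3.43 to 5.66) in immature cells. In mature cells the sum was at 2.40, with a wide interval (1.05 to 4.10). The immediate early and heat shock list had a median of 0.25 (0.11 to 0.35), with Hspa1a and Hspa1b higher and Egr2 lower (-1.40). Stfa2 (2.08, 1.76 to 2.42) and Stfa1 (0.96, 0.71 to 1.21), stefin protease inhibitors, were also among the 10 highest genes, as were Mpzl3 (1.20) and Adtrp (0.99). The lowest were Sdc2 (-0.90, -1.16 to -0.65), Lipt2 (-0.85), Thnsl1 (-0.81), Diras2 (-0.79), Zc3h6 (-0.78), Six5 (-0.78), Sqle, Lekr1 (-0.77), Enah (-0.76) and Acsl3 (-0.76), most of whose UMIs came from progenitor-like cells. Stfa1 was at 0.84 in immature and 0.71 in mature cells. Enah was at -0.73 in progenitor-like cells but at 2.05 in mature cells, which held 3 and 18 UMIs.

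Secreted factors through which neutrophils act on the regenerating marrow showed no member past the size rule. The list of regeneration-associated secreted factors had a median of -0.02 (-0.19 to 0.24, 13 genes), with Tgfb1 at 0.32 (0.16 to 0.48), Tnf at 0.23 (0.06 to 0.40) and Hgf at -0.38 (-0.59 to -0.16). Migration and retention genes stood at 0.17 (0.05 to 0.29), with the chemokine receptors Cxcr1 (1.12, 0.41 to 1.88) higher and Cxcr2 at 0.43 (0.39 to 0.46). Inflammatory mediators had a median of 0.23 (-0.03 to 0.33), with Il1b at 0.49 (0.40 to 0.57), Ccl4 at -0.52 and Cxcl10 higher (2.31, 22 and 133 UMIs). With cells thinned to 1000 UMIs, Cxcl10 turned to -1.20 (-3.89 to 1.16), on 5 and 3 UMIs. The alarmin list was at 0.30 (-0.04 to 0.92), with Stfa1, Stfa2, S100a4 (0.92) and Wfdc17 (0.91) higher, while S100a8 and S100a9 themselves were at 0.23 and 0.17. Wfdc17 was at 0.98 in mature cells but at -0.24 in progenitor-like and -0.98 (-2.07 to 0.06) in immature cells. With the stages weighted alike, the medians were 0.05 for alarmins, 0.07 for migration and retention, -0.01 for inflammatory mediators and 0.01 for the secreted factors. Within stages the medians of the secreted factors were -0.04, -0.09 and 0.18.

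In HSPC-like cells of the HFD library, 7 cholesterol synthesis genes were lower and some myeloid regulators higher, with the stem cell list near 0. The cholesterol and fatty acid synthesis list had a median of -0.52 (-0.65 to -0.25), below all matched random lists, with 7 of 24 members lower. Among these were Insig1 (-0.83, -1.09 to -0.57) and Sqle (-0.75, -1.09 to -0.41). Both are targets of SREBP2, the transcription factor of sterol synthesis. Acot1 was the highest of the ranked genes, which had at least 200 UMIs and no far higher level in another class (1.44, 1.20 to 1.69), and Cpt1a stood at 0.54 (0.43 to 0.65). The class held 647 ND and 554 HFD cells with median depths of 8276 and 8544 UMIs.

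Of the myeloid commitment list (median 0.07, -0.11 to 0.65), 3 of 18 members were higher: Id2 (1.08, 0.80 to 1.37), Gfi1 (0.68, 0.37 to 0.99) and Cebpb (0.68, 0.37 to 0.98), transcription regulators of the innate lineages. The haematopoietic stem cell list had a median of -0.08 (-0.20 to 0.24, 23 genes) with no member past the size rule. Mecom was at 0.02 (-0.25 to 0.29), Kit at -0.21, Hoxa9 at -0.27 and Ly6a, which encodes the surface antigen Sca-1, at 0.40 (0.21 to 0.59). Mitotic genes were shifted upwards, with a median of 0.24 (0.14 to 0.28) for the G2 and M phase list, 29 of 30 above 0, and 0.11 (0.05 to 0.18) for S phase. Lymphoid commitment was at -0.06 (-0.27 to 0.19) and erythroid and megakaryocytic commitment at -0.13 (-0.40 to 0.08).

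The type I interferon list was also higher in HSPC-like cells (median 0.39, 0.26 to 0.58, 7 of 28 members higher), with Cxcl10 at 3.77 (2.11 to 6.11, 3 and 36 UMIs), Rtp4 at 0.67 and Irf7 at 0.71. Other genes high in the ranking were Aspscr1 (0.95), Klhdc3 (0.86), Pdxk (0.83) and Rnaseh2a (0.82). Low in the ranking besides Insig1 were the linker histone gene H1f0 (-0.87, -1.02 to -0.72), Pbx4 (-0.80) and Zfand1 (-0.78). Ccl3 (-0.88, -1.12 to -0.65) and Pdgfa (-1.04, -1.92 to -0.21) were lower. Neutrophil transcripts were found here as well: Ngp (0.73), Camp (0.95), S100a8 (0.60) and S100a9 (0.61) were higher, and with doublets kept they turned to -1.04, -0.47, -0.09 and -0.13.

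Monocyte-like cells of the HFD library had higher Hspa1a (2.93, 2.79 to 3.07), Hspa1b (2.82), Shtn1 (1.73, 1.46 to 2.0), the integrin gene Itgax (1.71, 1.46 to 1.98) and the stress gene Ddit4 (1.54). Because the cluster mix differed, these genes were read within clusters as well. Hspa1a was at 3.34 in cluster 8 and 2.35 in cluster 24, and Hspa1b at 3.48 and 2.23. Shtn1 was at 1.64 in cluster 8 and 1.52 in cluster 24. Itgax was at 0.70 (-0.37 to 1.87, 36 UMIs in all) in cluster 8 and 1.23 (0.96 to 1.5) in cluster 24. Ddit4 was at 0.98 (-0.01 to 2.07) in cluster 8 and 1.12 (0.69 to 1.57) in cluster 24, so part of the ratios of Itgax and Ddit4 lay in the cluster mix. Genes low in the ranking were BC051226 (-0.85), H1f0 (-0.78), Ptbp2 (-0.76) and Fdxacb1 (-0.73).

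Macrophage-like cells had lower Cd209f (-1.57, -1.79 to -1.36), Nrp2 (-1.40, -1.76 to -1.04) and Timd4 (-1.03, -1.24 to -0.83), the last a phosphatidylserine receptor of resident macrophages, and higher Vsig4 (1.22, 0.97 to 1.47), a complement receptor. Both clusters had these directions: Timd4 was at -1.01 and -1.06, Cd209f at -1.39 and -1.68 and Vsig4 at 1.31 and 1.13 in clusters 19 and 21. Ifi27l2a, an interferon-inducible gene, was at 1.78 and the formyl peptide receptor gene Fpr1 at 1.16, and Stard4, a sterol carrier, at -0.96. The cholesterol and fatty acid synthesis list had a median of -0.48 (-0.59 to -0.12) and the G2 and M phase list one of -0.43 (-0.64 to -0.21).

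NK cell-like cells, fewer in the HFD library (417 and 223 cells), had lower Klra4 (-1.42, -1.62 to -1.21), an Ly49 receptor, lower Ccl4 (-0.91) and lower Cst7 (-0.85), with higher mitotic genes such as Ube2c (0.95, 0.65 to 1.24) and Cks2 (0.78). The S phase list was at 0.36 (0.26 to 0.59) and the G2 and M phase list at 0.28 (0.22 to 0.53). In conventional dendritic cell-like cells Cxcl9, a chemokine induced by interferon gamma, was at 2.52 (2.17 to 2.90), and in T cell-like cells Dnajb1 was at 1.12 (0.83 to 1.42).

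Several of these differences ran through the marrow. The type I interferon list had a median above 0 in 16 of 16 classes (0.13 to 0.77) and lay outside the central 95% of matched lists in 15. The cholesterol and fatty acid synthesis list lay below 0 in all 16 (-0.52 to -0.01), and outside that range in 12. The single genes that follow were chosen after their values were seen, and all classes come from the same 2 libraries. Their counts of classes are therefore a description and no test. Hspa1b was above 0 in 16 of 16 classes, with a median of 3.86, and Hspa1a in 14 of 14 with at least 20 UMIs, with a median of 4.04. The cold-inducible Cirbp was below 0 in 16 of 16 (median -0.63) and H1f0 in 15 of 16 (-0.75). Rbm3, also cold-inducible, stayed near 0, with a median of -0.03 (-0.22 to 0.20), above 0 in 5 classes and below it in 11. Tspo, a mitochondrial outer membrane protein, and Cpt1a were above 0 in 16 of 16 (0.78 and 0.67), Acot1 in 9 of 9 (1.51), Isg15 in 15 of 15 (1.12) and Oasl2 in 14 of 14 (0.99). Sqle was below 0 in 12 of 12 classes (-0.72) and Insig1 in 13 of 16 (-0.44). Genes encoded by the mitochondrial genome lay below 0 in all 16 classes, with a median of -0.11.

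**Figure D3:**
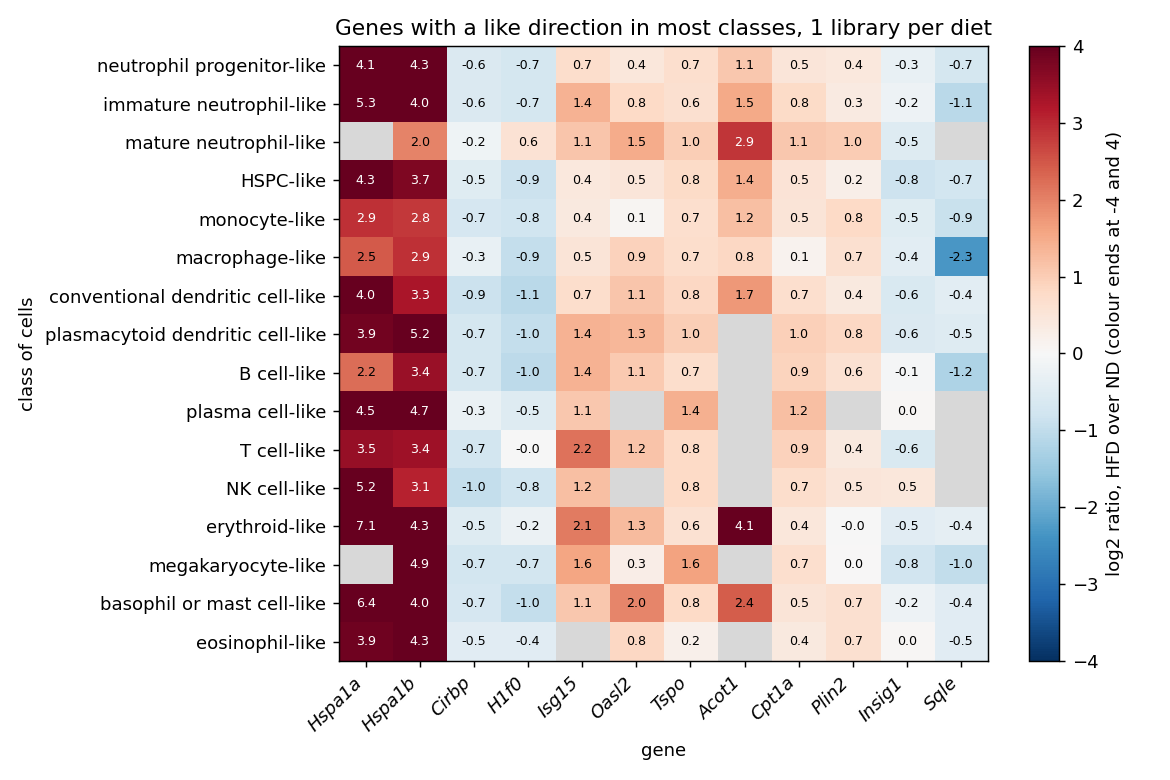
Log2 ratio of HFD over ND of 12 genes (columns) in 16 classes (rows); grey cells had under 20 UMIs. Hspa1b runs from 1.99 in mature neutrophil-like to 5.22 in plasmacytoid dendritic cell-like cells, and Cirbp from -0.95 to -0.16.

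Neutrophil transcripts in other cells differed between the libraries too. Outside the neutrophil stages, S100a8 was above 0 in 11 of 13 classes, with a median of 1.05, and the secondary and tertiary granule list in 11 (median 0.43). In the HFD and ND libraries, S100a8 and S100a9 in T cell-like cells stood at 2.19% and 1.41% of their level in the whole library, and in HSPC-like cells at 0.776% and 0.714%. Plasma cell-like cells ran the other way (S100a8 -1.87, -2.00 to -1.74), and so did megakaryocyte-like cells (-1.30). Haemoglobin transcripts made up 0.0048% and 0.0038% of UMIs in neutrophil-like cells of the ND and HFD libraries.

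Antibody tags were sparser in the HFD library, with 1308386 tag molecules against 2073137 and a median of 30 against 49 per cell. The tag for the Fc receptors CD16 and CD32 had a lower median per cell in all 16 classes, at a median ratio of 0.594 (0.385 to 0.683), and stood at 32 and 20 in mature neutrophil-like cells. The CD117 tag, for the stem cell factor receptor, had a median ratio of 0.657 in the 6 classes compared, and stood at 65 and 46 in HSPC-like cells. CD105 tags had a median ratio of 0.667 in 3 classes and phycoerythrin tags one of 1.00 in 5. Apart from megakaryocyte-like cells (25.5 and 26), the phycoerythrin medians compared were 1 or 2 molecules, too coarse to show a fall of that size. Mean phycoerythrin tags were 9.35 and 3.22 in neutrophil-like, 6.11 and 6.11 in HSPC-like and 59.5 and 110 in megakaryocyte-like cells. This tag is therefore no measure of an unchanged level. The Ly-6A tag median was 0 or 1 in the classes apart from plasmacytoid dendritic cell-like cells, where it was 1 and 2 (means 16.7 and 15.5), and megakaryocyte-like cells, where it was 0.5 and 0.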

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

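All alternatives were planned except leaving out neutrophil cluster 25, which was chosen after seeing the data. With 1 library per diet, depth limits only the counting error, and nothing here measures how animals or preparations vary. The ratios of shares kept within their counting intervals in 99 comparisons with an alternative and moved in 3. Ratios of single genes stayed within their intervals in 3456, moved in 451 and reversed in 29, list medians did so in 1654, 57 and 14, shares in percent held in 145 and moved in 59, and counts of classes held in 551 and moved in 7. No setting brought the median over all genes of a class further than 0.1 from 0. The furthest was -0.095, with every neutrophil-like cell weighted alike, against -0.016 with summed UMIs.

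The higher share of neutrophil-like cells, and of mature cells among them, held under each alternative, but the levels moved. With all cells as deposited the shares of neutrophil-like cells were 17.7% (ND) and 23.6% (HFD), a ratio of 1.33. The strict cell filter gave 21.9% and 27.1%, resolution 0.5 gave 22.8% and 28.1%, resolution 2.0 gave 19.8% in the ND library, and leaving out cluster 25 gave 18.7% and 24.1%. Mature cells were 26.8% and 34.7% of neutrophil-like cells at resolution 0.5 (ratio 1.30), 43.1% and 48.9% at resolution 2.0, and 33.7% and 41.6% without cluster 25. These follow from which cells or clusters enter the class. The ratio for conventional dendritic cell-like cells was 1.09 at resolution 2.0. The secondary and tertiary granule list in neutrophil-like cells stood at 0.028 with every cell weighted alike and at 0.039 with cells thinned to 1000 UMIs.

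Other values below turned sign. The 14 gene values turned by thinning rest on 1 to 38 thinned UMIs, 3 of them on the floor, and each interval included 0, so they show no direction. The thinned interval of Cxcl10 (-3.89 to 1.16, 5 and 3 UMIs) lay below its value from all UMIs, so few UMIs need not be the whole cause there. Thinning also gives each cell a like weight, and the 2 effects were not separated. For the rest the cause was not tested unless given. In neutrophil-like cells, weighting every cell alike gave -0.068 for the G2 and M phase list, and thinning gave -0.025. Thinning also turned Six5 (1.12), Lekr1 (0.024), Enah (0.15), Acsl3 (0.053), Il7r (0.19) and Cxcl10 (-1.20). Iigp1 and Vldlr (-2.05 each) held 0 ND and 1 HFD UMIs when thinned, so the floor of 3 alone set their sign. Weighting the stages alike turned Wfdc17 (-0.081) and Enah (0.031), whose stages differ, and Stfa1 (-0.076), Procr (-0.39) and Cfd (0.0028), which had 0 UMIs in a stage and library, so the floor enters. Resolution 0.5 turned H2-Aa (0.60). In progenitor-like cells the free haemoglobin list was at 0.26 at resolution 0.5 and with every cell weighted alike. In immature cells the nuclear oxidative phosphorylation list was at 0.0018 with thinning. In mature cells the mitochondrially encoded list was at 0.057 with the strict filter, 0.028 with cells weighted alike and 0.0039 with thinning. The immediate early and heat shock list was at -0.0078 at resolution 0.5 and -0.0064 without cluster 25, which also gave 0.021 for free haemoglobin. Keeping doublets gave 0.75 for MHC class II and -0.074 for the niche and adipocyte list.

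In HSPC-like cells, keeping doublets turned the secondary and tertiary granule list (-0.037), Chil3 (-0.029), Camp (-0.47), Ngp (-1.04), S100a9 (-0.13) and S100a8 (-0.089), and thinning turned Ngp (-0.51), Ifitm6 (-0.77), Fcgr4 (-0.36), Pdgfa and Lss (0.23 each). Elsewhere, keeping doublets turned S100a9 in monocyte-like (-0.080) and S100a8 in NK cell-like cells (-0.41), resolution 2.0 turned Stk3 in B cell-like cells (0.70), weighting cells alike turned Rsad2 (-0.11) and thinning turned Cpt1c (0.41) in erythroid-like cells. The cause was not tested, apart from Fcgr4, which held 0 ND and 2 HFD UMIs when thinned, so that the floor set its sign.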

Other observations

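Tests of the wider heat-shock response, of library handling, of equal free RNA in every cell and of the Acot pair class by class were chosen after their results were seen, and the tests of PPAR targets and of the Acot pair over 16 classes were read anew afterwards. Plasmacytoid dendritic cell-like cells had the largest interferon median of the classes but 1 (0.77, 0.15 to 1.14), with Ly6a at 1.45 (1.30 to 1.59) and Cd4 at 1.26 (1.03 to 1.5) higher and Cd209a (-1.16, -1.38 to -0.94) and Ccr2 (-0.72) lower. Their Ly-6A tag had a median of 1 in the ND and 2 in the HFD library, but a mean of 16.7 and 15.5. Basophil or mast cell-like cells had lower Egr2 (-1.66, -1.95 to -1.38), Egr3 (-1.12) and Egr1 (-1.05, -1.09 to -1.02), with the immediate early and heat shock list at -0.04 (-0.34 to 0.20), and higher Il3ra (0.71), a receptor for interleukin 3. Plasma cell-like cells had lower Mt2, a metallothionein (-1.18, -1.32 to -1.05), and lower Egr1 (-1.03), and higher class II genes H2-Eb1 (0.84) and H2-Ab1 (0.75).

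Megakaryocyte-like cells (146 and 113 cells) of the HFD library had higher Ppbp (2.38, 2.31 to 2.46), Gp6 (2.47, 2.03 to 2.93), Myl9 (2.18) and Mpig6b (2.09), with the erythroid and megakaryocytic commitment list at 0.21 (0.04 to 0.71). Their CD117 tag had a median of 54.5 (ND) and 26 (HFD) and a lower quartile of 18.5 and 1. The make-up of this class may thus differ between the libraries, and its part in these ratios was not tested. Erythroid-like cells had the largest Acot1 ratio (4.09, 3.64 to 4.58, 43 and 488 UMIs), with Isg15 at 2.06 (1.79 to 2.34) and Adam33 lower (-1.46). Their cluster mix differed, with 47.7% of ND and 59.1% of HFD cells in cluster 0 and 38.1% and 26.6% in cluster 1, where Acot1 was at 3.82 and 5.58 and Isg15 at 1.05 and 1.21, against 2.43 for Isg15 in the smaller cluster 16. Adam33 was at -1.09 in cluster 1. B cell-like cells had higher Cpt1a (0.89, 0.71 to 1.08) and Cd36 (0.85) and lower Reln (-0.81). Eosinophil-like cells had higher Ralb (1.14, 0.73 to 1.56) and lower Slc7a8 (-0.87). Over the classes, medians of list medians were 0.04 for glycolysis, 0.03 for nuclear oxidative phosphorylation, 0.02 for the oxidative stress response, 0.09 for ER stress, -0.10 for MHC class II, -0.03 for niche and adipocyte genes and -0.16 for free haemoglobin transcripts.

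3 clusters took no name. Cluster 3 (3.32% and 3.11% of ND and HFD cells) had Dntt and Flt3 among its top genes, cluster 4 (3.03% and 2.65%) Gzmb and Muc13, and cluster 27 (1.79% and 1.16%) Gata3 and Il1rl1.

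The first pattern is the higher Hspa1a and Hspa1b in the HFD library, which encode near-identical proteins. Moving UMIs between the paralogs cannot raise both, and both were higher. Their summed UMIs, at a median log2 ratio of 3.72 over 16 classes (2.40 to 6.34), therefore had to be high and add no test. They show that the pair as a whole was higher, while the split of UMIs between the 2 genes was not tested. Free RNA was not tested for this pair. Hspa1b stood at 463 CPM in the ND and 2166 CPM in the HFD cells of monocyte-like cluster 24. How far free RNA enters the ratios of classes with few UMIs stays open. A heat-shock response that raises most other chaperones 1.5-fold or more is argued against: the 20 other chaperones had a median of 0.084 over 16 classes, and each interval ended below that size. A response of a few chaperones would not move this median. In their highest class Dnajb1 stood at 1.12 and Hsp90aa1 at 0.69, but Hspa8 and Hsph1 at 0.48. A response of a few chaperones stays open, and so does a smaller one, since the chaperone median was above 0 in 14 of 16 classes. Handling of the library and the diet cannot be told apart with 1 library per diet, and either may be the source.

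The second pattern is the higher type I interferon list in 16 of 16 classes. The test of free RNA first written, with S100a8 and S100a9 as its measure and the whole library as its profile, left it open: the supply stayed below the need in 12 of 13 classes but not in plasma cell-like cells, where it was 10.5% against 8.93%. A later test, added because of that outcome, argues only against equal free RNA in every cell as the whole source, since the gain in UMIs per 1000 cells ran from 234 in eosinophil-like to 4158 in megakaryocyte-like cells, whose depths also differ. The 1% of cells with the highest interferon share are argued against as the whole source. Without them the median over classes was 0.43, against 0.40 with all cells. Single classes moved both ways, from 0.35 to 0.24 in neutrophil progenitor-like and from 0.27 to 0.41 in B cell-like cells. Ranking by share favours cells of low depth, and a larger responding minority was not removed, so strongly responding cells beyond this 1% stay open. Free RNA in part, and handling of the library against the diet with 1 library per diet, stay open, so a response to the diet may be proposed only as a hypothesis.

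The third pattern joins higher Acot1 and Cpt1a with a lower cholesterol synthesis list. The first test of free RNA again left it open, with the supply below the need in 18 of 19 pairs of gene and class, and the later one argues only against equal free RNA in every cell as the whole source, with gains per 1000 cells up to 563 for Acot1 and 957 for Cpt1a against 28.8 and 8.91 in the lowest classes. The test of UMIs shared with Acot2 first written gave a median of 0.52 for the summed pair over 16 classes. It decides nothing because 7 of them do not hold Acot1. Of the 9 that do, 6 had a sum more than 1.5-fold higher, so their median (1.14) had to lie above that size. In these 6 the sum argues only against UMIs merely moved from Acot2 to Acot1 as the whole source. Such a move stays open in 3 (0.21), of which neutrophil progenitor-like cells had a sum of 0.55 (0.39 to 0.71), above 0. A higher Acot2 whose UMIs were counted as Acot1 would raise the sum too, and the split of UMIs between the 2 genes was not tested. Action through PPAR stays open: other PPAR target genes lay above the central 95% of matched lists in only 4 of 16 classes, which met the bound set beforehand against it, but that bound was wrong because a list short of it is not excluded, and 15 of 16 medians were above 0 and the lowest percentile was 68.9. Handling of the library and the diet cannot be told apart with 1 library per diet, and either may be the source.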
